A study of Solanum lycopersicum with 12 samples.

How the data were processed

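Small RNAs of tomato cotyledon (day 0) and of callus (days 12, 14 and 16 on SIM medium) were sequenced by the authors in 12 libraries, 3 per group. Per the labels' protocols, adapters were ligated to RNA ends with T4 RNA ligases, the products were reverse transcribed and amplified by PCR, and fragments were selected on a gel. Per the submitters' processing notes the tools were fastp, Bowtie and DESeq2; their versions, their settings and the genome build were not given in the sources used here. How reads that map to several loci were counted was also not given in the sources used here, which matters for loci with similar sequences. Reads without molecular identifiers are not independent molecules.

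The authors deposited 3 tables. The first held raw counts per gene locus in 108 columns, 1 for each of 9 read lengths from 18 to 26 nt in each library, per the file headers, and its values were whole numbers. The second held TPM values of sense and antisense gene reads by length and library, per the file headers. The deposited TPM were scaled to a library total larger than the gene reads, since dividing gene counts by TPM gave 1 constant per library. With that constant, all 216 deposited TPM values came out as whole reads within 0.05 reads, and the constant was used as the recovered library total. The third held the authors' own DESeq2 comparisons for each length, with log2 fold changes, p-values and adjusted p-values deposited by the authors. No unused columns of other samples were present (0).

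Groups and replicate numbers came from the sample titles. Each library was counted as 1 sample, as labelled. Replicates of a group differed by more than counting noise (chi-square over degrees of freedom 3.61 to 12.4), so that none was a copy of another file, but PCR copies alone can give such values, which do not show separate cultures. The labels gave no batch or date. Gene reads per library ranged from 456744 to 698312 and recovered library totals from 2769024 to 4799134.

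Comparisons, tests, the rule for named loci, the lists and most alternatives were fixed before the data were examined. The main test was edgeR's quasi-likelihood F test over all 12 libraries with TMM scaling, filterByExpr and Benjamini-Hochberg adjustment at 0.05. The count unit of the fixed design did not foresee separate read lengths, and counts were summed over 18 to 26 nt for the main results and also tested per length. After filtering, 6729 loci were tested, and the common biological coefficient of variation was 0.333. The 18 length and strand classes of the TPM table were tested with limma on log2(TPM + 1). The pseudocount was 1, and the fold changes are on that scale. Shares of reads were compared by exact permutation tests, two-sided, over the 9 callus and 3 cotyledon libraries, which cannot give a p below 0.00455; between groups of 3 the limit is 0.10. SE of an edgeR log2 change was taken as the change over the square root of its F statistic. A fold against a group without reads used a floor of 3 counts over the group.

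Loci were named by this rule: in each comparison, among loci with an adjusted p under 0.05, a mean of at least 10 CPM over both groups and no overlap between the groups' libraries, the 8 with the largest rise and the 8 with the largest fall (5 and 5 among callus times), reduced to at most 2 per direction for identifiers without a name, which held for all of them. At most 4 members per fixed list, with a name, and any feature of a table of 40 features or fewer were also allowed. Loci outside the rule are said to have been chosen after their values were seen; the 1 list member described has no name and is likewise outside it. The lists of microRNA families (phase change, auxin signalling, shoot meristem and organ boundary, leaf growth, copper and lignin, nutrients, small RNA machinery and resistance genes) and of gene descriptions (photosynthesis, cell cycle, histones, cytokinin, auxin, shoot meristem, transcription factor families targeted by microRNAs, root and vascular tissue, epidermis, wounding and defence, small RNA machinery and ribosomal proteins) matched no feature, because the loci carry identifiers without names or descriptions. The 8 identifiers of the shoot meristem and organ boundary list were found. As 1 passed the filter, no set test was run and no adjustment over the list alone was made.

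Choices made after the tables were seen were the sum over lengths, the classes of loci by most frequent length, over all libraries or by 1 group alone, the test of 24-nt against 21-nt change within loci (a library term plus length-by-group terms, 774 loci with enough reads of both lengths), the measures without abundant loci, ranked over all libraries or within groups, the comparison of all callus with cotyledon libraries, the scaling by library totals, keeping 1 locus per near-identical set and leaving out 3 callus libraries, or these and 1 cotyledon library, that stood apart on the second principal component. Near-identical sets were loci with at least 100 reads whose counts differed by at most 5% of their mean total; 24 sets with 49 loci held 9.73% of reads. The alternatives set beforehand were DESeq2 size factors, the DESeq2 Wald test, no filter, a filter of 10 CPM in 3 libraries, a replicate block, a fit of the 6 libraries compared, other pseudocounts for TPM, and leaving out each replicate.

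The tests were first run on simulated values with known changes. Summed counts were drawn with the means, dispersions and library sizes of the real libraries. For limma, normal log2 values were drawn with the same SD for all classes, each class independently of the others. For the 24-nt against 21-nt test, counts of each length were drawn separately with a fixed dispersion, not that of the real libraries. For day 16 against day 12 in 6729 loci, edgeR recovered 2% of 2-fold and 57% of 4-fold changes and 9.23% of its calls were false, against 7%, 59% and 9.59% for DESeq2. For day 14 against cotyledon, edgeR recovered 10% and 55% with 11.0% false calls, and DESeq2 12% and 60% with 4% false calls. The false shares of edgeR lay above the nominal 5%. limma recovered 100% of 4-fold changes in 18 classes with 0% false calls, and the 24-nt against 21-nt test recovered 43.3% of 4-fold changes in 774 loci with 10.3% false calls. The changes found in the real classes were smaller than 4-fold, and classes of 1 library may move together. The limma simulation therefore does not show the power or the false calls for them. With all libraries simulated without change, those of cotyledon included, at most 2, 1 and 1 loci were called at the 3 callus times in 20 draws.

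The analysis used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.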

Results

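Small RNAs were sequenced from tomato (Solanum lycopersicum) cotyledons, the seed leaves, taken 6 days after sowing, and from the callus that formed when such cotyledons were kept on SIM medium. The 12 libraries fell into 4 groups of 3, namely cotyledon at day 0 and callus at days 12, 14 and 16. The deposited table gave reads of 18 to 26 nt at 34688 gene loci, of which 32258 had a read in some library. Gene loci held between 456744 and 698312 reads per library, out of library totals of 2769024 to 4799134 reads that were recovered from the deposited TPM values. What that total counts (clean, genome-mapped or length-filtered reads) was not given in the sources used here, and the meaning of every share of library reads and of every change relative to the library totals depends on it. A value here is the number of small-RNA reads placed on a gene, which is not the level of its mRNA. In plants, reads of 21 and 22 nt are typical of microRNAs and secondary small interfering RNAs, and reads of 24 nt of the small interfering RNAs that direct DNA methylation. The labels did not say whether replicates came from separate cultures, so that p-values measure the spread between these libraries only, which may be technical.

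The first question was how the small RNAs over genes differed in length and strand between cotyledon and callus. Relative to the library totals, gene reads of 23 and 24 nt fell on both strands at all 3 callus times. Sense 24-nt reads fell from 22278 ± 2799 TPM in cotyledon to 14397 ± 291 at day 12, 14544 ± 567 at day 14 and 13861 ± 731 at day 16 (SD, n = 3). Antisense 24-nt reads fell from 18169 ± 2859 TPM to 11793 ± 186, 12485 ± 388 and 12296 ± 352 (SD, n = 3). Sense reads of 22, 25 and 26 nt also fell at the 3 times, sense reads of 18 to 20 nt fell at days 14 and 16, and antisense 26-nt reads fell at the 3 times.

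Reads of 21 nt did not pass the test on either strand at any callus time. Their log2 changes were 0.24, 0.18 and -0.06 for sense and 0.19, -0.14 and 0.0050 for antisense reads. The 21-nt reads include those of Solyc11g008540.3 and of the pair Solyc12g040470.2 and Solyc03g119020.2, described below. Without that pair, 21-nt reads of both strands were 40177 to 65255 TPM in cotyledon. At days 12, 14 and 16 they were 52479 to 55219, 31714 to 47258 and 43923 to 54087. Solyc11g008540.3, still included, held more of the gene reads in callus. The test was not run without these loci, so that a fall of 21-nt reads elsewhere stays open. In limma on log2(TPM + 1), 8 of the 18 length and strand classes passed an adjusted p of 0.05 at day 12, 12 at day 14 and 12 at day 16, and all of these fell. For sense 24-nt reads the log2 change was -0.62 at day 12 (SE 0.11, adjusted p = 0.000932), -0.61 at day 14 (adjusted p = 0.000720) and -0.68 at day 16 (adjusted p = 0.000289). Without replicate 3 of callus day 12, 5 classes passed at day 12. Antisense 22-nt reads passed at days 14 and 16 with adjusted p of 0.0453 and 0.0451, calls that were lost in 5 of the 9 alternatives at each time, where adjusted p ranged from 0.000559 to 0.167 at day 14. Other calls were lost without 1 library, in limma adjusted p: sense 26 nt at day 12 without replicate 1 or 3 of cotyledon or 2 or 3 of callus (up to 0.115), sense 25 nt at day 12 without replicate 3 of callus (0.0530), and sense 18 and 19 nt at day 16 without replicate 2 or 3 of cotyledon or 1 or 2 of callus (up to 0.129 and 0.0709). Antisense 26 nt was lost without replicate 1 of cotyledon at days 12 and 14, and without callus replicates 1 or 3 at day 12, 2 or 3 at day 14 and 1 or 3 at day 16 (limma adjusted p up to 0.123, 0.129 and 0.0537).

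**Figure D1:**
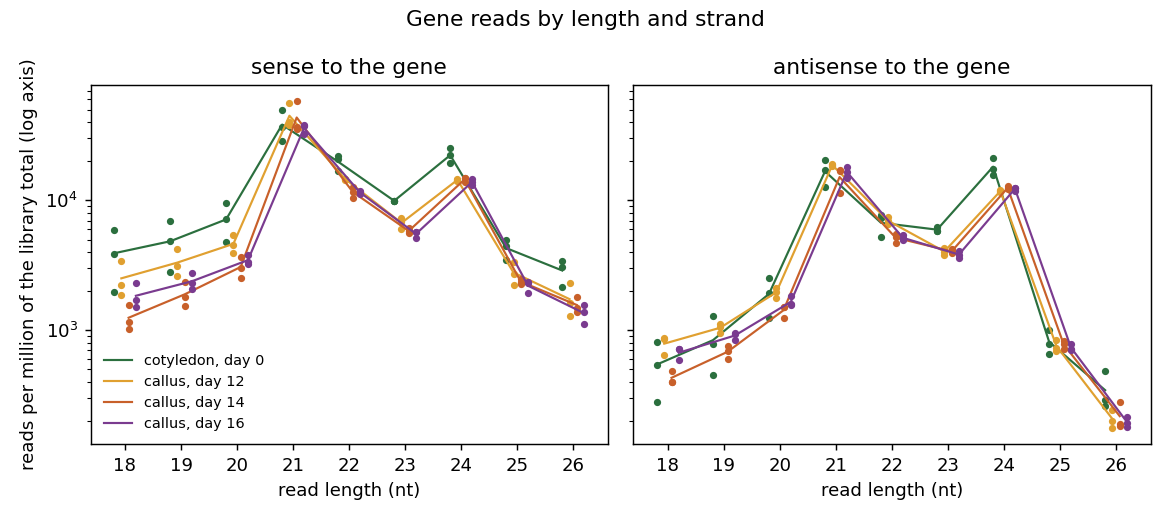
TPM, relative to the library total (log axis), against read length in nt for sense (left) and antisense (right) gene reads; points are single libraries, lines join the means of the 3 libraries of a group, and colours mark cotyledon and the callus times. All 9 callus libraries lay below all 3 cotyledon libraries for antisense 24-nt reads, while at 21 nt the groups overlapped.

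The share of a library's reads that lay on genes was lower in callus. It was 16.5% ± 1.83 in cotyledon, and 14.2% ± 0.607, 12.6% ± 1.73 and 12.0% ± 0.211 in callus at days 12, 14 and 16 (SD, n = 3). Over the 9 callus and 3 cotyledon libraries the exact permutation test (two-sided) gave p = 0.00909, or 0.0295 after Benjamini-Hochberg adjustment over 13 library measures. Among gene reads, the 21-nt share was 32.9% in cotyledon and 44.8% in callus (exact permutation p = 0.00455, adjusted 0.0295). The ratio of 24-nt to 21-nt reads was 0.788 ± 0.311 in cotyledon and 0.467 ± 0.0794 in callus (exact permutation p = 0.0136, adjusted 0.0355). Whether both held depended on which abundant loci were left out. Without the 10 loci with the largest mean share in cotyledon, the 21-nt share was 26.7% and 41.4% and the ratio 1.21 ± 0.508 and 0.574 ± 0.102 (exact permutation p = 0.00455 for each). Rankings that include callus reads take out loci that rose there, such as Solyc11g008540.3 below, and so remove part of the difference by construction. The ranking by cotyledon alone leans the other way, as it lowered the 21-nt share more in cotyledon than in callus. Ranked by the mean of both group means, the 21-nt share was 27.4% and 29.4% (exact permutation p = 0.359, and 0.532 for the ratio). Without the 10 loci of cotyledon and the 10 of callus, it was 23.2% and 24.5% (exact permutation p = 0.505, and 0.641 for the ratio). Without the 10 loci with the most reads over all libraries, 9 of which were callus, the 21-nt share was 28.0% and 28.4% (exact permutation p = 0.859), the 24-nt share 29.5% and 29.6% (exact permutation p = 0.991) and the ratio ranged from 0.719 to 1.54 and from 0.868 to 1.57 over the libraries (exact permutation p = 0.895). Between 2 groups of 3 libraries such a test cannot give a p below 0.10.

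**Figure D2:**
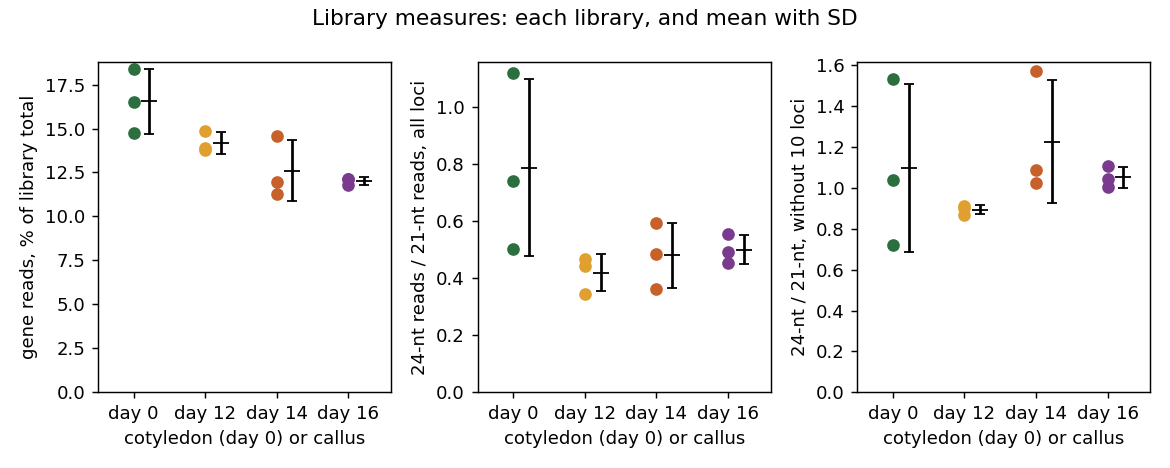
Gene reads as a percent of the library total (left), the ratio of 24-nt to 21-nt gene reads over all loci (middle) and that ratio without the 10 loci with the most reads (right), by day; coloured points are single libraries and black bars the mean and SD of 3. The ratio averaged 0.788 in cotyledon and 0.467 in callus over all loci; without those 10 loci it ranged from 0.719 to 1.54 in cotyledon and from 0.868 to 1.57 in callus.

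A locus rich in 21-nt reads rose in callus to a large share of all gene reads. Solyc11g008540.3, with 82.1% of its reads at 21 nt, rose from 8542 ± 3885 CPM of gene reads in cotyledon to 94425 ± 6674 at day 12, 87273 ± 21252 at day 14 and 101860 ± 37493 at day 16 (SD, n = 3). It held 0.376% to 0.929% of the gene reads of the cotyledon libraries and 6.30% to 12.1% of those of the callus libraries. The rise was 11.1-fold, 10.2-fold and 11.9-fold, with log2 changes of 3.47, 3.35 and 3.58 (SE 0.37, 0.37 and 0.38; edgeR adjusted p = 1.93e-06, 3.16e-06 and 1.54e-06). This locus was chosen after its values were seen. The files did not pair locus identifiers with gene names, and 0 identifiers matched the gene table given with the reference, so that loci are named by identifier only and at most 2 per direction.

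Callus at day 12 was compared with cotyledon to ask which loci had gained or lost small RNAs by the first callus time. Of 6729 loci tested, 967 rose and 1289 fell. Solyc03g115920.3, with 60.2% of its reads at 21 nt, had 0 reads in the cotyledon libraries and 83 to 330 in callus, at least 141-fold higher. Solyc07g009500.3, whose reads were spread evenly over 18 to 26 nt, had 0 reads in cotyledon and 59 to 111 in callus, at least 74.0-fold higher. Solyc07g042230.1, with 94.0% of its reads at 21 nt, fell from 484 to 1149 reads per cotyledon library to 0 or 1 in callus, and Solyc06g160050.1 fell from 51 to 75 reads to 0, at least 76.7-fold lower. Reads of Solyc06g160050.1 were also spread over 18 to 26 nt, with 5.38% to 18.3% at each length. Whether reads at loci without a main length are small RNAs or fragments of transcripts was not tested.

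The test at day 12 was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, which gave adjusted p = 0.000115 and 5.28e-06 for the 2 loci that rose and 2.88e-08 and 1.49e-06 for the 2 that fell. The 2 callus reads of Solyc07g042230.1 against 2440 in cotyledon gave a ratio of 0.000659 (95% exact counting interval 7.98e-05 to 0.00238). DESeq2 called 2156 loci. Over all 6729 loci tested, the libraries of the 2 groups did not overlap at 46.6%, against 10% by chance. Without replicate 2 of callus day 12, Solyc03g115920.3 was at least 83.8-fold higher. All folds given as at least a value were computed against a floor of 3 counts over the group, which 1 library fewer in the group without reads lowered by at most 1.62 times, and floors and intervals cover counting error only.

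At day 14, 943 loci rose and 1164 fell. Solyc03g115920.3 was at least 153-fold higher than in cotyledon, with 33 to 415 reads per library, but at least 39.5-fold without replicate 3 of callus day 14, which held the 415 reads. Solyc07g009500.3 was at least 56.6-fold higher, with 23 to 98 reads. Solyc07g042230.1 had 0 reads in the 3 libraries and was at least 896-fold lower, and Solyc06g160050.1 likewise had 0 reads and was at least 67.9-fold lower. Adjusted p in edgeR was 8.94e-05 and 1.17e-05 for the rises and 2.31e-08 and 2.18e-06 for the falls. DESeq2 called 1998 loci, and the groups did not overlap at 44.9% of the loci tested (10% by chance).

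At day 16, 904 loci rose and 1175 fell. Solyc07g009500.3 was at least 134-fold higher, with 71 to 219 reads per library. Solyc07g009510.1, the identifier that follows it in number, had 0 reads in cotyledon and 58 to 153 in callus, at least 96.8-fold higher. Its reads were likewise spread over all lengths from 18 to 26 nt, with 8.95% to 13.3% at each. Solyc07g042230.1 again fell, to 0 to 2 reads per library, a ratio of 0.000780 from 2 callus reads, both in replicate 2 (95% exact counting interval 9.44e-05 to 0.00282). Solyc08g082160.3, with 82.4% of its reads at 24 nt, fell from 12 to 35 reads per cotyledon library to 0, at least 24.2-fold lower. Adjusted p in edgeR was 1.50e-06 and 1.74e-06 for the rises and 2.93e-08 and 0.000196 for the falls. DESeq2 called 1968 loci, and the groups did not overlap at 44.4% of the loci tested (10% by chance).

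The balance of rises and falls in these comparisons depended on what reads were scaled to. With TMM scaling of gene reads the median log2 change over all loci was 0.08, 0.10 and 0.11 at days 12, 14 and 16. With the library totals as the scale it was 0.01, -0.24 and -0.24, and 830 loci rose and 1361 fell at day 12, 566 and 1598 at day 14, and 519 and 1564 at day 16. The share of calls that rose was then 37.9%, 26.2% and 24.9%, against 42.9%, 44.8% and 43.5% with TMM. Replicate 3 of day 12, replicate 1 of day 14 and replicate 3 of day 16 stood apart from the other callus libraries on the second principal component, at 13.6, 43.1 and 33.1 against -23.0 to -8.27, as did replicate 1 of cotyledon from the other cotyledon libraries, at 17.3 against -9.32 and -7.11. Without the 3 callus libraries 2227 loci were called for callus day 12 against cotyledon day 0, 1980 for callus day 14 against cotyledon day 0 and 1977 for callus day 16 against cotyledon day 0, and without all 4 libraries 1792, 1599 and 1659.

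Most loci called at one callus time were called in the same direction at the others. Across the 3 times, 579 loci rose and 892 fell throughout, and 0 loci rose at one time and fell at another. Independent lists of these sizes would share 18.2 and 38.9 loci. Simulated groups without any change shared 0 and 0. With at most 2, 1 and 1 calls they could hardly share any, so that they do not show how lists of these sizes would overlap. The comparisons used the same 3 cotyledon libraries, which were too few to split, so that part of the excess may come from the shared controls.

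With loci as the unit, those that rose and fell differed in their main read length at days 12 and 16, and at day 14 only by some ways of classing and scaling them. Among 2089 loci whose most frequent length over all 12 libraries was 21 nt, 480 rose and 273 fell at day 12, 366 and 311 at day 14, and 355 and 277 at day 16. Among 3290 loci with mostly 24-nt reads, 220 rose and 763 fell at day 12, 370 and 571 at day 14, and 342 and 617 at day 16. The odds of a rise against a fall were 6.09 times higher for 21-nt than for 24-nt loci at day 12 (95% interval 4.91 to 7.58, Fisher's exact test, two-sided, p = 5.22e-69), 1.82 times at day 14 (1.48 to 2.23, p = 5.52e-09) and 2.31 times at day 16 (1.87 to 2.85, p = 9.31e-16). Loci are not independent replicates, and the classes were set after the table was seen. With libraries as the unit, the median log2 level of 21-nt less that of 24-nt loci, classed by cotyledon reads, was compared relative to the library totals. It did not pass over the 9 callus and 3 cotyledon libraries (exact permutation p = 0.105). Day 12 libraries (0 to 0.23) lay above those of cotyledon (-0.81 to -0.12), while those of day 14 (-0.45 to -0.18) and day 16 (-0.33 to -0.18) overlapped them. As 9 of the 12 libraries were callus, the class of a locus that rose rested largely on the reads that rose. With loci of at least 10 cotyledon reads classed by these alone, falls outnumbered rises among 21-nt loci at the 3 times (178 rose and 220 fell, 138 and 259, and 135 and 229), and the odds were 3.77 times higher at day 12 (2.88 to 4.95, Fisher's exact p = 2.30e-23), 1.04 times at day 14 (0.799 to 1.34, p = 0.797) and 1.34 times at day 16 (1.03 to 1.75, p = 0.0273). This class leans the other way, since the minimum leaves out loci that rose from few cotyledon reads. Loci of 21 nt went from 2089 to 1264, and those of 24 nt from 3290 to 3002. The excess of falls is thus built in to an unknown degree. The same minimum applied to the library medians above. For loci with the same class in cotyledon and callus, again with that minimum, the odds were 6.39, 1.33 and 1.66 times higher (Fisher's exact p = 8.95e-30, 0.0704 and 0.00132). With the library totals as the scale these odds were 3.84, 1.48 and 1.81 by cotyledon reads (Fisher's exact p = 6.14e-22, 0.0120 and 0.000227) and 6.44, 2.12 and 2.19 for the same class (p = 4.11e-28, 2.16e-05 and 2.74e-05), so that the outcome at day 14 changed with the scale. With the library totals as the scale and classes over all libraries, falls outnumbered rises among 21-nt loci at day 14 (242 rose, 427 fell) and day 16 (228 rose, 377 fell), but not at day 12 (418 rose, 290 fell), and among 24-nt loci 189 rose and 811 fell, 185 and 837, and 160 and 855 at the 3 times.

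**Figure D3:**
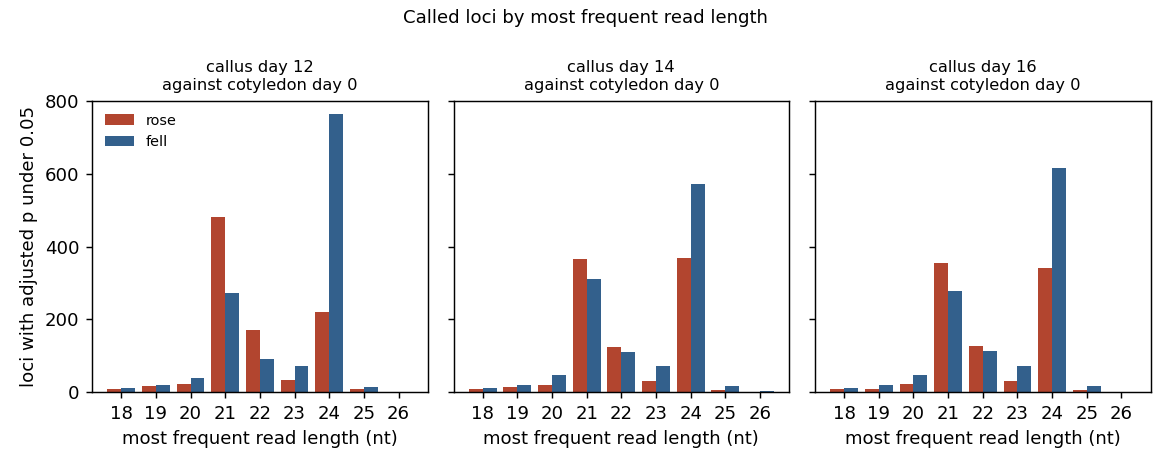
Number of loci with an edgeR adjusted p under 0.05 that rose (red bars) or fell (blue bars) against the most frequent read length of the locus over all 12 libraries in nt, 1 panel per callus time against cotyledon. At day 12, 480 loci of 21 nt rose and 273 fell, while 220 loci of 24 nt rose and 763 fell; with library totals in place of TMM, falls outnumbered rises at 21 nt too at days 14 and 16.

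Within loci that carried both lengths, the balance of 24-nt and 21-nt reads changed in both directions. Of 774 such loci, 22 shifted towards 24 nt and 51 towards 21 nt at day 12, 34 and 37 at day 14, and 26 and 49 at day 16. This edgeR test compared the 24-nt with the 21-nt change inside each library, so that library scaling cancels. At day 16, 46 loci passed in place of 75 without replicate 1 or without replicate 2 of callus day 16.

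Loci of a list of 8 shoot meristem and organ boundary genes, fixed by identifier beforehand, carried few reads. 1 of the 8, Solyc07g062840.3, passed the filter, with 164 reads in all and 70.7% of them at 21 nt. It rose from 2.85 ± 3.36 CPM in cotyledon to 27.6 ± 26.9 at day 12, 46.3 ± 10.7 at day 14 and 32.0 ± 21.3 at day 16 (SD, n = 3), with log2 changes of 3.09, 3.88 and 3.36 (SE 0.91, 0.87 and 0.90; edgeR adjusted p = 0.0145, 0.00257 and 0.00862). The other 7 had 0 to 34 reads over the 12 libraries, and changes in them were not detectable at this depth. For Solyc07g062840.3, callus day 12 against cotyledon day 0, the call was lost without replicate 1 or 3 of cotyledon (log2 2.91 and 2.64), without replicate 3 of callus day 12 (1.99), without the 3 callus libraries that stood apart (2.03) and without these and replicate 1 of cotyledon (1.81), with adjusted p between 0.000325 and 0.218 over the alternatives.

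The remaining comparisons asked what changed among the callus times. Between days 12 and 14, and between days 14 and 16, edgeR called 0 of 6729 loci (602 and 356 at an unadjusted p under 0.05), while DESeq2 called 17 and 2. Between days 12 and 16, 4 loci rose and 0 fell (571 at an unadjusted p under 0.05; 14 in DESeq2). Solyc04g074450.1 rose from 2.41 ± 2.58 to 42.7 ± 13.4 CPM (log2 4.03, SE 0.71, edgeR adjusted p = 0.0387), and Solyc00g500353.1 from 4 to 15 reads per library to 45 to 61 (log2 2.90, SE 0.45, edgeR adjusted p = 0.0299; SD, n = 3). The other 2, named after their values were seen, were Solyc03g042560.3 (log2 2.62, SE 0.46) and Solyc06g074030.1 (log2 2.87, SE 0.50), each with an edgeR adjusted p of 0.0387.

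These 4 calls were lost with library totals as the scale and with the replicate block. Those of Solyc04g074450.1, Solyc03g042560.3 and Solyc06g074030.1 were also lost without the 3 callus libraries that stood apart, or without these and replicate 1 of cotyledon. When any 1 of the 6 libraries was left out, 0 to 2 loci were called. No length and strand class passed in limma between callus times (0 of 18 in each of the 3 comparisons, with 6, 0 and 3 at an unadjusted p under 0.05 for day 14 against 12, 16 against 14 and 16 against 12; no other tool was run). Solyc11g008540.3 differed by -0.11, 0.22 and 0.11 on the log2 scale in these comparisons (SE 0.34; edgeR adjusted p = 0.940, 0.992 and 0.961). In simulated counts for day 16 against day 12, edgeR recovered 57% of 4-fold and 2% of 2-fold changes, so that changes of 2-fold would mostly have gone unseen.

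Tested length by length against cotyledon, 349 of 2358 loci rose and 402 fell in 24-nt reads at day 12, 360 and 391 at day 14, and 353 and 408 at day 16. For 21-nt reads, of 989 loci tested, 229 and 217, 243 and 226, and 220 and 209 rose and fell. With the library totals as the scale these counts were 160 and 711, 167 and 630, and 154 and 680 for 24-nt reads, and 191 and 221, 135 and 320, and 152 and 271 for 21-nt reads. Among callus times, edgeR called 4 loci for 20-nt reads (day 16 against 14, all lower; 21 at an unadjusted p under 0.05; 4 in DESeq2; 1 with library totals; 0 without replicate 2 of day 14 or of day 16) and 2 for 26-nt reads (day 14 against 12, both higher; 6 at an unadjusted p under 0.05; 0 in DESeq2, 0 with library totals, and 0 without any 1 library other than replicate 1 of day 14). In the authors' deposited table, 572, 575 and 589 loci passed for 24-nt reads and 351, 344 and 309 for 21-nt reads at days 12, 14 and 16. Of these, 513, 504 and 508 and 286, 284 and 266 were tested here, and all of them had the same direction in both analyses. Both used the same libraries, so that a shared direction is not independent evidence. Of the 751, 751 and 761 loci called here for 24-nt reads, 493, 489 and 490 were called by both. For 21-nt reads it was 284, 283 and 266 of 446, 469 and 429.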

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

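The comparison of day 16 with day 12 was planned, while leaving out 3 or 4 libraries together, the scaling by library totals and the look at read lengths were chosen only after the result was seen.

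At 4 loci the change from cotyledon differed between callus at day 12 and at day 16, by the test of that difference itself. Solyc04g074450.1 was higher at day 16 by 4.03 on the log2 scale, Solyc00g500353.1 by 2.90, Solyc06g074030.1 by 2.87 and Solyc03g042560.3 by 2.62, with values above those of day 12 in all 3 day 16 libraries. The reads of these loci were spread over many lengths, with the most frequent length holding 17.5% to 21.2% of reads, against a median of 38.7% over the tested loci; 22.4% of tested loci were spread as evenly. Of the 10 splits of these 6 libraries, 1 gave as many calls, the real one, and the highest of the others gave 1 call, but 10 splits are too few for a share under 0.05. Over the alternatives, edgeR and DESeq2 adjusted p ranged from 5.80e-05 to 0.229 for Solyc04g074450.1, 9.08e-07 to 0.137 for Solyc00g500353.1, 4.11e-05 to 0.217 for Solyc03g042560.3 and 0.000712 to 0.224 for Solyc06g074030.1. All 4 calls were lost with library totals as the scale and with the replicate block. No explanation for these 4 differences was tested.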

How the results depend on the processing

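Scaling by library totals, classing loci by the reads of 1 group, 1 locus per near-identical set and leaving out 3 callus libraries, or these and replicate 1 of cotyledon, together were chosen only after the result was seen; the other alternatives were planned. Total counts of loci against cotyledon stayed within 1.5 times under the 16 alternatives, at 1792 to 2500 for callus day 12 against cotyledon day 0, 1599 to 2355 for callus day 14 against cotyledon day 0 and 1659 to 2359 for callus day 16 against cotyledon day 0 (2120, 1956 and 1949 with the replicate block). With library totals, however, loci that rose went from 943 to 566 at day 14 and from 904 to 519 at day 16. The small counts between callus times moved. For callus day 14 against callus day 12, edgeR gave 0 loci, the DESeq2 Wald test 17, no filter 36, and leaving out 1 library 0 to 1. For callus day 16 against callus day 14, edgeR gave 0, DESeq2 2, no filter 32, leaving out the 3 libraries 11, leaving out the 4 libraries 9, and leaving out 1 library 0 to 2. For callus day 16 against callus day 12, edgeR gave 4, DESeq2 14, no filter 51, library totals 0, the replicate block 0, and leaving out 1 library 0 to 2. The cause was not tested.

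The length and strand classes at day 12 (8 of 18) ranged from 5 to 10 when 1 library was left out, 5 without replicate 3 of callus day 12; those at days 14 and 16 (12) from 10 to 14 and from 8 to 13. The cause was not tested. No called change of a named locus or class changed sign, but with library totals falls outnumbered rises among called loci dominated by 21-nt reads at day 14 (242 rose, 427 fell) and day 16 (228 and 377), and the median log2 change of all loci went from 0.10 and 0.11 to -0.24 and -0.24. The odds of a rise for 21-nt against 24-nt loci at day 14 (1.82) did not pass with classes by cotyledon reads (1.04) or with the same class in both groups (1.33) under TMM, but passed with library totals (1.48 and 2.12). Of values for single loci 336 stayed on their side of the threshold and 45 did not, of single classes 257 and 31; of counts for single lengths 632 stayed within 1.5 times and 70 moved. Besides the 4 loci of day 16 against day 12, the replicate block moved no count of loci or classes over all lengths by over 1.5 times; libraries with the same number were not taken as paired, since 4 of 18 such pairs had a correlation of deviations over 0.1 (r -0.263 to 0.195). Pseudocounts and a filter on low TPM were not run for counts, to which they do not apply, nor alternatives of the fixed lists, for which no set test was run. At this depth 6729 of the 32258 loci with a read passed the filter on counts and could be tested. With these library sizes, dispersions and 3 replicates, edgeR recovered 57% of simulated 4-fold changes between days 12 and 16; depth alone was not varied.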

Other observations

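The 9 against 3 comparison, the count of loci with reads and all tests of the gene share and of the matching pair were chosen only after the result was seen; the test of neighbouring loci and the counts of splits were set before.

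Small RNAs covered more gene loci in callus than in cotyledon. At a common depth of 456744 gene reads, 18316 ± 134 loci were expected to carry a read in cotyledon, and 21091 ± 721, 20795 ± 393 and 20941 ± 486 in callus at days 12, 14 and 16 (SD, n = 3). All 9 callus libraries (20307 to 21726) lay above the 3 cotyledon libraries (18162 to 18409; exact permutation test, two-sided, p = 0.00455, the smallest it can give). At the same time reads were more concentrated: the 10 most abundant loci of each library held 21.9% of gene reads in cotyledon and 32.5% in callus (exact permutation p = 0.00909, adjusted 0.0295 over 13 measures). Solyc12g040470.2 and Solyc03g119020.2, described below, may count the same reads at both loci. Together they held 0.918% to 2.71% of gene reads in cotyledon and 0.826% to 20.9% in callus, which can raise this share in callus. Their reads, 94.1% of them at 21 nt, also enter the 21-nt share given above.

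The strand split of the shortest reads also differed. Antisense reads made up 17.2% ± 0.0619 of the 18 to 20-nt gene reads in cotyledon, and 28.7% ± 3.06 in callus (SD, n = 3 and 9), higher in all 9 callus libraries (exact permutation p = 0.00455, adjusted 0.0295). At 21 nt and 24 nt the antisense share did not pass that test (30.6% and 29.2%, exact permutation p = 0.586; 44.9% and 46.1%, exact permutation p = 0.173, for cotyledon and callus).

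A smaller share of library reads lay on genes in callus. Fragments of the genes' own transcripts, which are sense, are excluded as the whole cause of its 24-nt part. Antisense 24-nt reads fell too, with log2 changes of -0.53 or lower and all 9 callus libraries below the 3 cotyledon libraries. A part from fragments in the sense fall stays open (log2 changes of -0.62, -0.61 and -0.68 for sense and -0.61, -0.53 and -0.55 for antisense reads at days 12, 14 and 16). A few loci abundant in cotyledon stay open: without the 10 loci with the largest mean share there, the share was 11.8% to 14.1% in cotyledon and 10.1% to 12.9% in callus (n = 3 and 9; exact permutation p = 0.0636). Chosen as high in cotyledon, these loci lower cotyledon most by construction (3.57% of library reads held there, 1.755% in callus). Without the 10 loci with the most reads over all libraries, a ranking that leans towards callus, the share was 12.4% to 14.7% in cotyledon and 7.67% to 10.4% in callus. Fragments may account for the 18 to 20-nt part, as antisense changes exceeded sense changes by at least 0.83 on the log2 scale, but antisense reads were also lower at day 14 (-0.29). At 26 nt antisense reads fell too (log2 changes of -0.63 or lower, 8 of 9 callus libraries below every cotyledon library), which goes against fragments as the whole cause there without excluding them. More reads outside genes would lower every class by 1 factor, which cannot change the antisense share at 18 to 20 nt. That share differed (exact permutation p = 0.00455), so that something else changed too. This split cannot tell whether more reads outside genes account for the lower total share, which stays open. That such reads lowered most loci alike stays open as well. The median log2 level of 21-nt less that of 24-nt loci, classed by cotyledon reads, was -0.46 ± 0.347 and -0.15 ± 0.206 (SD, n = 3 and 9, exact permutation p = 0.105). A biological difference between cotyledon and callus stays open, untested.

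Solyc12g040470.2 and Solyc03g119020.2 had matching counts in all 12 libraries and together ranged from 0.826% to 20.9% of the gene reads of a callus library. Their counts differed by at most 0.222% of the mean in any library, which is consistent with the same 21-nt reads being counted at both loci. Library size is excluded as the cause of the range, which was 26.5 times relative to the library total, and so is a shift of all 21-nt reads, since those of the other loci ranged 1.74 times. Day of culture is excluded as the whole cause, since the libraries of day 12 alone ranged 21.1 times (573 to 12092 RPM), and stays open in part (exact permutation test of the spread between days over 1680 assignments, p = 0.343). The pair was highest of its day in 2 of the 3 callus libraries that stood apart on the second principal component (12092 RPM at day 12, 4450 at day 16), but not at day 14 (8082 against 15221), and what sets these libraries apart stays open (r = 0.611 with that component within days, exact permutation p = 0.116 over 216 orders).

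Called loci lay next to each other in the order of identifiers more often than by chance. At day 16 against cotyledon, 200 of 1980 neighbouring pairs of tested loci were called in the same direction, against 95.9 on average over 10000 permutations (one-sided permutation p = 1e-04, the smallest they can give). Reads shared between near-identical loci are excluded as the whole cause, since with 1 locus per set the ratio of observed to permuted pairs was 2.04, against 2.08 for all loci. Reads shared in part between neighbours, and overlapping genes, stay open, since no coordinates were used here. A biological explanation was not tested.

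All callus libraries together against cotyledon gave 2707 loci, of which 1224 rose and 1483 fell, and 2170 to 2958 without 1 library. Only 1 of 100 drawn splits into 9 and 3, the real one, gave as many calls, and the highest of the others gave 37. This argues against a random division of these libraries as the source of the count. It does not address whether replicates were separate cultures. The other splits mixed callus with cotyledon libraries, which added their difference to the spread. Hence 37 is not the number of calls to be had without a difference. Splits of 3 against 3 libraries number 10 and are too few for a share under 0.05. Those of callus against cotyledon mix the groups in the same way. For days 12, 14 and 16 against cotyledon, 1, 1 and 1 of the 10 splits gave as many loci as the real 2256, 2107 and 2079, with 0, 0 and 0 in the highest other split, and 1, 1 and 1 gave as many length and strand classes as the real 8, 12 and 12, with 3, 5 and 2 in the highest other. Between callus times 10 of 10 splits gave at least the 0 loci called for day 14 against 12 (highest other 0) and for day 16 against 14 (highest other 4), and likewise 10 of 10 for the 0 classes called in each of the 3 comparisons (highest other 0; 6, 0 and 3 classes had an unadjusted p under 0.05 in limma, and edgeR gave 602 and 356 loci at that level, with 17 and 2 in DESeq2).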
